A study of Nitrosomonas europaea ATCC 19718 with 12 samples.

How the data were processed

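Total RNA of Nitrosomonas europaea, a bacterium that lives on the oxidation of ammonia to nitrite, was measured on 1-colour Agilent oligonucleotide arrays made for this species. Per the labels, cells grown in a chemostat were moved in volumes of 300 mL to bottles, given ammonium to 50 mg/L as NH3-N, and shaken for 6 h at 28 °C in the dark. The bottles held no particles, 10 mg/L ZnO nanoparticles, 50 mg/L TiO2 nanoparticles, or both at the same doses. These are 4 groups with 3 scanner files each, 12 in all. Per the labels, RNA was labelled with Cy3 after linear amplification, and independent experiments gave the replicates.

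The scanner files hold each spot's intensity on a linear scale, extracted by the authors with Agilent Feature Extraction 11.0.1.1, per the file headers. The signal used here is the processed signal deposited in those files, after the scanner software's own background treatment. Each array carried 14616 spots that were not controls, which are 2436 probes with 6 spots each, 1 probe per ID. Of these IDs, 2389 are locus tags that start with NE and 47 start with RNA. The authors also deposited a table of log2 values for 2428 of the 2436 IDs. Its columns had medians of 8.65 to 8.66 and an equal maximum of 18.4, and each column correlated at 0.997 or more with the scanner values of its own array across IDs. Its values are therefore uncentred per ID and run in the direction of the signal. The nearly equal columns look like those of a quantile normalization, while the background treatment behind them is not given in the sources used here.

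The files pair no ID with a gene name or product. Nothing here is named beyond its ID for that reason, and 19 of the 20 gene lists written before the data were examined, which select by symbol or product, could not be used. The remaining list holds 16 locus tags set down from background knowledge as loci of ammonia and hydroxylamine oxidation, nitrite and nitric oxide reduction, carbon fixation and mercury reduction. No file bears out that assignment, so it is called the fixed list below. The arrays had a probe for 12 of its tags and none for 4. Of these, NE0945 and NE2064 had nearly equal mean levels in every group, such as 5.96 and 5.99 in control and 7.34 and 7.31 with nano-ZnO. They may not be separate measurements, though each counts as 1 tag below. Other IDs, such as NE0162, NE0188 and NE0254, were also nearly equal, and whether such probes read the same sequence was not tested.

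Values were log2 of the processed signal minus the 75th percentile of each array over spots that were not controls. Spots with an outlier flag were left out, 108 to 351 per file, and the 6 spots of a probe were averaged. A probe counted as well above background when at least 3 of its spots did. IDs were tested if this held on all files of at least 1 group, which kept 2424 and left out 12. On each file 98.6 to 99.8% of spots were well above background and no spot was saturated. The 75th percentile of the signal ran from 894 to 1693, and the median coefficient of variation between spots of a probe from 3.28 to 4.09%.

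The files were compared before averaging. Spot comparisons used the 1400 probes with a mean level above -2, and for correlations spot deviations were cut off at 1 log2 unit either way. Within every group, replicates 1 and 3 had the same slide row and column in the file headers and came from different scans. The deviations of single spots from their probe's median correlated at 0.807 to 0.897 between replicates 1 and 3, against 0.260 to 0.564 between replicate 2 and either of them and 0.162 to 0.465 between groups. The median squared difference over spot variance was 0.187 to 0.317 for replicates 1 and 3, and 3.75 to 18.7 for replicate 2 against them. Spot noise independent between arrays would give 0.455, and less where spot deviations are shared. Replicates 1 and 3 of each group, alike in slide position and spot deviations, were counted as 1 array, their mean. This leaves 2 arrays per group and 8 arrays. The design fixed before the data were examined had 12 separate arrays, and that fit is given only among the alternatives. All 8 positions of 1 scan, 2 rows by 4 columns, were in use, and each group had 2 neighbouring positions of its own. The row is shared by control with nano-ZnO and by nano-TiO2 with the mixture.

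Group means were fitted with limma 3.58.1 in R 4.3.3 over all 8 arrays, which gives 4 residual degrees of freedom and 3.64 prior degrees of freedom. IDs were called at a Benjamini-Hochberg adjusted p under 0.05 from limma's moderated test, and the number that also reached 2-fold is given beside it. Each treatment was set against control, the mixture against each single particle, and the interaction was the mixture minus nano-ZnO minus nano-TiO2 plus control on the log2 scale. The comparison of nano-TiO2 with nano-ZnO was added after the data were examined. The fixed list was tested with camera at a preset correlation of 0.01, beside the set of 47 IDs that start with RNA, which was chosen after the data were examined. Adjusted p-values of these tests run over both sets within a comparison. Comparisons that share the control arrays were set beside 100 simulated draws of unchanged groups. Correlations were also computed with 1 control array for each comparison, a check chosen after the data were examined, which leaves no spread within the control.

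The fit was tested on simulated data before use, in 10 runs with 200 changed IDs each. For nano-ZnO against control it called 88.9% of true log2 changes of 0.5 and 99.2% of changes of 1, and 0.36% of unchanged IDs. The real comparison called 81.1% of IDs, and with so many calls the share of unchanged IDs called can be higher. The simulated noise was independent with the fitted spread, and neither the scaling of arrays nor variation between cultures was simulated. The number of arrays limits the precision, and the median standard error of a log2 change was 0.0897, or 0.127 for the interaction. P-values rest on the spread between 2 arrays of a group, pooled over the 4 groups and moderated. The labels call these arrays independent, but the files do not tie them to separate cultures. The median SD within a group was 0.064 for control, 0.038 for nano-ZnO, 0.086 for nano-TiO2 and 0.087 for the mixture. A pooled spread may therefore be too small for the mixture against nano-TiO2.

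The rule for IDs to name was also set before the data were examined and allowed more of them. Because the files pair no ID with a gene, it was reduced to the 2 largest rises and 2 largest falls among the called IDs of each comparison, plus the 2 rising and 2 falling members of the fixed list with the largest changes against control. In every comparison but the interaction, an ID named by size also had to have the arrays of both groups apart. All named IDs were well above background on every array. For 11 tested IDs, not well above background in at least 1 group, a change is only a bound. Alternatives were quantile normalization, median centring, the authors' table, no filter, a stricter filter, normexp background correction with an offset of 50, the replicate number as a block, a variance trend, array weights, only the groups compared, and each array left out. The files hold no mean signal, so normexp used the median signal. Normexp in that form, the 12 separate files, the first scan alone, the scan as a block and kept outlier spots were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the files and drew the figures.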

Results

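Transcript levels of Nitrosomonas europaea were measured after 6 h without particles, with 10 mg/L nano-ZnO, with 50 mg/L nano-TiO2, or with both. The series asks how the particles act on gene expression alone and combined. Each of the 4 groups was represented by 2 arrays. The files labelled replicates 1 and 3 of each group shared a slide position, had closely correlated spot deviations and were counted as 1 sample. Signals well above background covered 98.6 to 99.8% of spots per file, and 2424 IDs were tested.

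**Figure D1:**
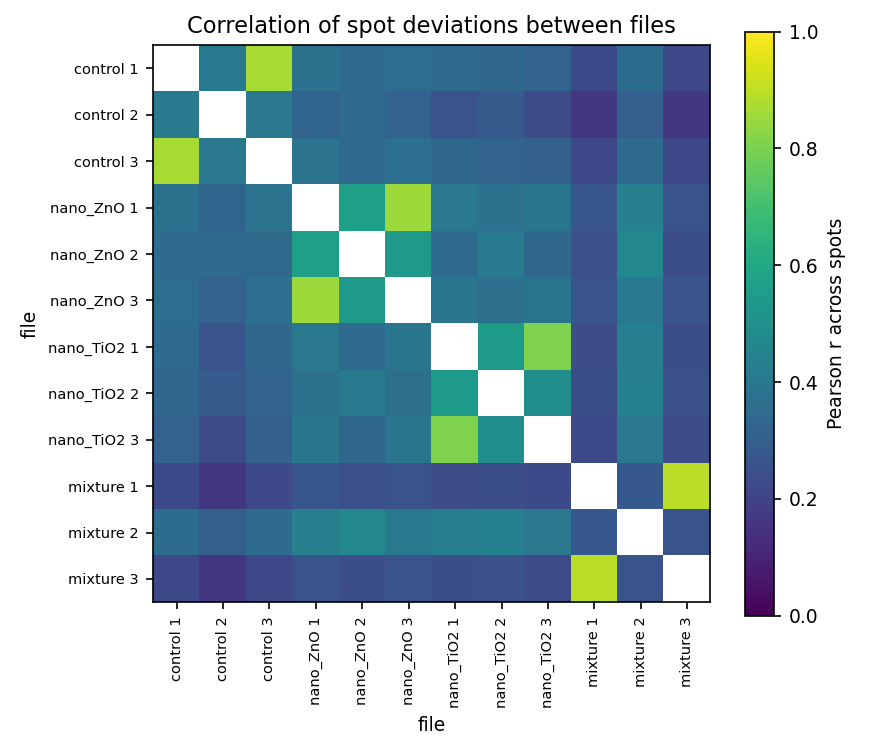
Pearson correlation, across spots, of each spot's deviation from the median of its probe, for every pair of the 12 files (both axes: files by group and replicate; colour: r). Spots of the 1400 probes with a mean level above -2 were used, with deviations cut off at 1 log2 unit either way. Replicates 1 and 3 of each group lie at 0.807 to 0.897, and all other pairs at 0.564 or below.

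Arrays of 1 group correlated at 0.996 to 0.999 across IDs. Arrays of different treated groups correlated at 0.970 or more, and control arrays correlated with treated arrays at 0.868 to 0.881. These correlations run across IDs, which are not independent replicates.

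With nano-ZnO, set against control to ask what this particle did alone, NE2039 rose by 3.64 on the log2 scale (SE 0.08, limma adjusted p = 1.22e-08), from a level of -3.97 ± 0.10 to -0.34 ± 0.05 (SD, n = 2 arrays). NE2292 rose by 3.24 (SE 0.11). NE0922 fell by 6.62 (SE 0.11), which is 98.3-fold, and NE0918 fell by 5.73 (SE 0.14), which is 53.0-fold. Of the 12 measured tags of the fixed list, whose assignment to functions was not checked, 7 rose, 4 fell and 1 was not called, and 11 were called when adjusted over the list alone. NE2003 rose by 2.41 (SE 0.09) and NE0943 by 2.31 (SE 0.10), while NE0924 fell by 2.82 (SE 0.11) and NE1411 fell by 2.46 (SE 0.11), and these 4 kept their direction under every scaling tried, with -1.60 for NE1411 under quantile normalization. Of the 2424 IDs, 1965 were called by limma at an adjusted p under 0.05, of which 944 rose and 1021 fell, with 354 and 536 of them by 2-fold or more; under quantile normalization 1099 rose and 887 fell. The list as a whole was not called against the other IDs (camera adjusted p = 0.427, and adjusted p = 0.870 with an estimated correlation).

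With nano-TiO2 alone, NE2039 rose against control by 3.55 (SE 0.08, limma adjusted p = 1.43e-08, n = 2 arrays per group) and NE0510 by 3.26 (SE 0.12). NE0922 fell by 6.21 (SE 0.11) and NE0918 fell by 6.06 (SE 0.14). On the fixed list 6 tags rose, 4 fell and 2 were not called, with 10 called when adjusted over the list alone. NE2003 rose by 2.22 (SE 0.09) and NE0943 by 1.47 (SE 0.10), or by 2.76 under quantile normalization. NE0924 fell by 4.11 (SE 0.11) and NE1411 fell by 2.71 (SE 0.11). Calls covered 1939 IDs, with 1038 that rose and 901 that fell, and 335 and 445 of these did so by 2-fold or more. The list's median change was 0.16 and its mean -0.35, and the set test, whose direction was down, did not call it (camera adjusted p = 0.969, and adjusted p = 0.984 with an estimated correlation).

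With both particles together, NE2039 rose against control by 3.47 (SE 0.08, limma adjusted p = 2.02e-08, n = 2 arrays per group) and NE0510 by 3.22 (SE 0.12). NE0922 fell by 5.85 (SE 0.11) and NE0918 fell by 5.82 (SE 0.14). The fixed list had 6 tags that rose, 4 that fell and 2 not called, and 10 were called when adjusted over the list alone. NE2003 rose by 2.36 (SE 0.09) and NE0943 by 1.61 (SE 0.10), while NE1411 fell by 2.65 (SE 0.11) and NE0924 fell by 1.77 (SE 0.11). Under quantile normalization NE0943 rose by 2.76 and NE0924 fell by 0.74. The mixture changed 1957 IDs, of which 1033 rose and 924 fell, 344 and 448 of them by 2-fold or more. The list's median was 0.43 and its mean -0.06, and it was not called as a set (camera adjusted p = 0.668, and adjusted p = 0.823 with an estimated correlation).

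**Figure D2:**
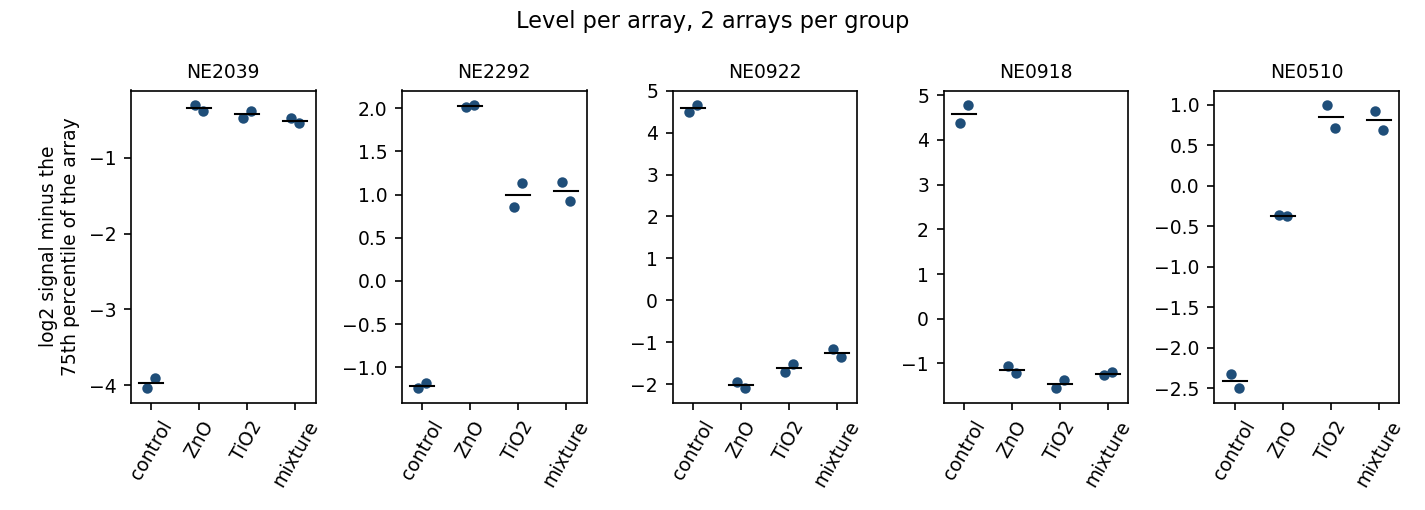
Level of the 5 IDs named for the comparisons against control, as log2 signal minus the 75th percentile of the array, with a scale of its own for each ID. Points are the 2 arrays of a group and lines their mean; NE0922 fell from 4.59 in control to -2.03 with nano-ZnO.

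The 3 comparisons against control shared most of their calls. In all 3, 800 IDs rose and 780 fell, of which 197 and 376 did so by 2-fold or more each time, while 160 IDs were called in none. Fold changes under nano-ZnO and nano-TiO2 correlated at 0.912 across IDs, those under nano-ZnO and the mixture at 0.919, and those under nano-TiO2 and the mixture at 0.967. Unchanged groups simulated against the same controls gave 0.501, 0.499 and 0.505. The covariances were 1.32, 1.31 and 1.32, against simulated covariances of 0.0066, 0.0066 and 0.0067. Both single particles raised 824 IDs and lowered 799, where independent lists would share 404 and 380, and 52 IDs went in opposite directions. Simulated unchanged groups shared a mean of 0.03 calls. With 1 control array for each comparison, so that none was shared, the correlations were 0.896 and 0.903, 0.905 and 0.909, and 0.956 and 0.952 for the 2 ways to assign them. Part of the excess may still come from what both control arrays have in common.

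**Figure D3:**
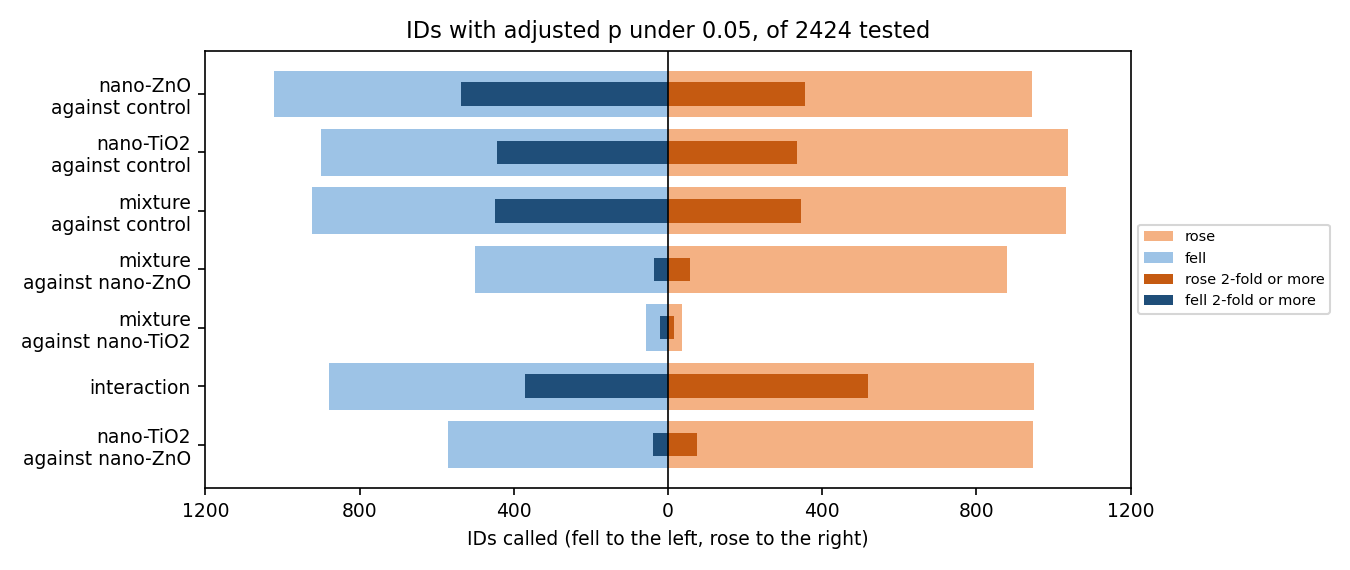
Number of IDs called at adjusted p under 0.05 in each comparison (x axis: IDs, those that fell to the left and those that rose to the right; wide bars: all calls; narrow bars: calls of 2-fold or more). The comparisons against control call 1939 to 1965 IDs, and the mixture against nano-TiO2 calls 94.

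The mixture was set against nano-ZnO to ask what nano-TiO2 added to it. NE0871 rose by 1.82 (SE 0.26, limma adjusted p = 0.00121, n = 2 arrays per group) and NE0927 by 1.81 (SE 0.08). NE1538 fell by 2.87 (SE 0.16) and NE0980 fell by 2.24 (SE 0.22). On the fixed list 1 tag rose, 6 fell and 5 were not called, and 7 were called when adjusted over the list alone; under quantile normalization 2 rose and 4 fell, and NE0943, which fell by 0.70 (SE 0.10), had a change of 0.11 with no call. NE0924 rose by 1.04 (SE 0.11), to a level that stayed below control. Calls covered 1380 IDs, of which 880 rose and 500 fell, with 56 and 37 of them by 2-fold or more. The list was lower as a set (camera adjusted p = 0.00136), a call lost under quantile normalization (adjusted p = 0.406) and with an estimated correlation (adjusted p = 0.298). The share of calls that rose was 63.8%, and 50.3% after median centring, which moved the median of all IDs from 0.09 to -0.01.

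The mixture was set against nano-TiO2 to ask what nano-ZnO added to it. NE2153 rose by 3.43 (SE 0.07, limma adjusted p = 1.31e-07, n = 2 arrays per group), which is 10.8-fold, and NE1452 by 3.37 (SE 0.07). Levels of NE2153 were 3.03 in control, -0.18 with nano-ZnO, -2.225 with nano-TiO2 and 1.21 with the mixture. Its rise is thus a smaller fall from control than with nano-TiO2 alone. NE1452 was at 2.11 in control, -0.93 with nano-TiO2 and 2.44 with the mixture. NE1539 fell by 2.64 (SE 0.11) and NE1538 fell by 2.21 (SE 0.16). On the fixed list NE0924 rose by 2.33 (SE 0.11), under every scaling tried, to a level that stayed below control. The other 11 tags were not called, and 1 was called when adjusted over the list alone. Calls covered 94 IDs, of which 36 rose and 58 fell, 15 and 20 of them by 2-fold or more, while 403 IDs had an unadjusted p under 0.05. The list was higher as a set (camera adjusted p = 0.0156), but adjusted p = 0.425 with an estimated correlation, adjusted p = 0.140 under quantile normalization, and adjusted p = 0.125 without mixture replicate 2. The share of calls that rose was 38.3%, and 50.0% of 126 calls under quantile normalization. The fit of all 12 files as separate arrays called 564 IDs, and that of only these groups called 62.

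Between the single particles, NE0871 was higher with nano-TiO2 than with nano-ZnO by 1.86 (SE 0.26, limma adjusted p = 0.000827, n = 2 arrays per group) and NE1436 by 1.81 (SE 0.08). RNA_47 had a log2 change of -2.11 (SE 0.15), or -1.07 under quantile normalization, and NE2153 one of -2.04 (SE 0.07). Of the fixed list, 9 tags were lower and 3 were not called, with 9 called when adjusted over the list alone, while under quantile normalization 1 was higher and 3 were lower. The particles differed at 1518 IDs, with 946 higher under nano-TiO2 and 572 lower, 74 and 40 of them by 2-fold or more. The list was lower as a set (camera adjusted p = 2.44e-05), but adjusted p = 0.143 with an estimated correlation and adjusted p = 0.132 under quantile normalization. The share of higher calls was 62.3%, and 48.3% after median centring. Among the 114 IDs that differed by 2-fold or more, the mixture lay at a median position of 0.86 between nano-ZnO at 0 and nano-TiO2 at 1, with quartiles of 0.68 and 0.95. The mixture and nano-TiO2 also shared a slide row, in which nano-ZnO had no array. Their closeness, here and in the number of calls, cannot be told apart from an effect of the row.

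The interaction, which asks whether the mixture departs from the sum of the single changes on the log2 scale, was largest at NE0927, which lay above the sum by 7.23 (SE 0.12, limma adjusted p = 1.74e-08, n = 2 arrays per group), and NE0922 lay above it by 6.98 (SE 0.15). NE2039 had an interaction of -3.72 (SE 0.11) and NE2292 one of -3.20 (SE 0.15). On the fixed list 4 tags lay above the sum, 6 below and 2 were not called, and 10 were called when adjusted over the list alone; NE0924 lay above it by 5.15 (SE 0.15) and NE2003 had -2.26 (SE 0.12). Under quantile normalization 2 tags lay above and 7 below. The interaction was called at 1827 IDs, 948 above the sum and 879 below it, with 519 and 370 of them by 2-fold or more, and under quantile normalization 830 lay above and 1019 below. The list's median was -0.65 and its mean 0.03, and it was not called as a set (camera adjusted p = 0.696, and adjusted p = 0.975 with an estimated correlation). The interaction opposed the summed single changes in sign at 1807 of the 1827 IDs, or 98.9%. Control, nano-ZnO and nano-TiO2 enter both quantities with opposite signs. Opposite signs therefore follow wherever all treated groups lie close together on 1 side of control. A shift of the control arrays alone would give the same, also for the ratios that follow. Among the 1623 IDs called in the same direction under each particle alone, the mixture change was a median of 0.48 of the summed change, with quartiles of 0.41 and 0.55, and 0.86 of the larger single change. Among the 195 IDs called under neither particle alone, 10 had an interaction call. The mixture was called above control and each single particle at 4 IDs, and called below each of these groups at 26.

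**Figure D4:**
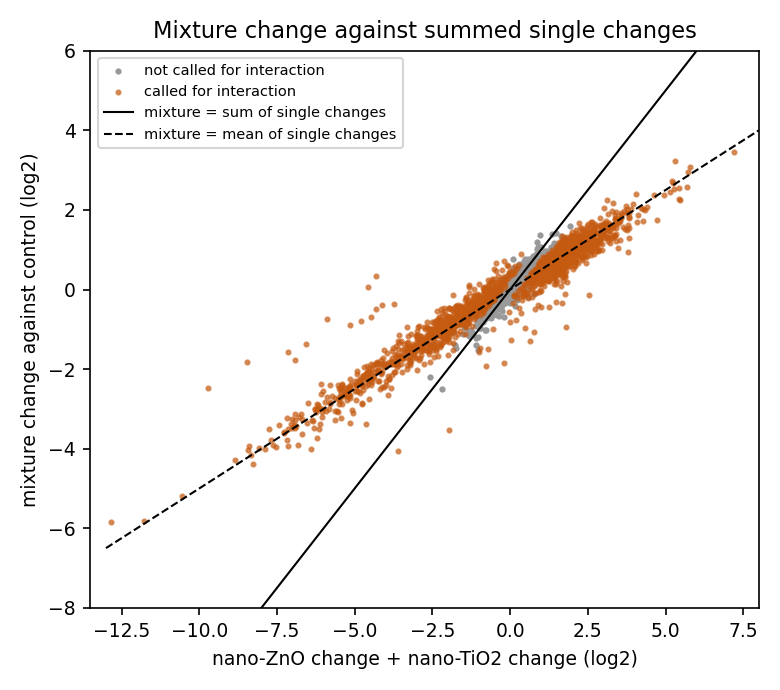
Log2 change under the mixture against control (y axis) and the sum of the log2 changes under nano-ZnO and nano-TiO2 alone (x axis), 1 point per ID, with the 1827 IDs called for interaction in orange. The solid line marks the sum and the dashed line the mean of the single changes; the points follow the dashed line, with a slope of 0.95 on the mean single change.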

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

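The tests of scaling, slide position, control shift, measured range and rescanning were chosen only after the results were seen. The effect of nano-ZnO differed with and without nano-TiO2 at 1827 IDs by the interaction term, at 10 of the 12 measured tags of the fixed list, and at the IDs with the largest interactions, NE0927 (7.23), NE0922 (6.98), NE2039 (-3.72) and NE2292 (-3.20).

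The interaction opposed the summed single changes at 1807 IDs. Groups simulated with additive changes and the fitted spread gave at most 1 such call in any of 20 draws, which argues against noise of the arrays. The simulation took the control levels as measured, so it says nothing on a shift of the control cultures. A floor or ceiling of the signal would leave IDs with room for the additive level without such calls, but 1565 of the 2145 IDs whose additive level lay at least 1 log2 unit inside the measured range had them. Of the 242 opposite calls nearer to the limits or beyond, 171 had a mixture level at least 1 log2 unit inside the range. A limit would not hold the mixture there, and NE0922 and NE0927 are among these 171. For the other 71 a limit of the signal and a response that does not add up cannot be told apart, because the mixture level also lay there. A shared response that either particle already brings close to its full size stays a hypothesis.

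All 3 treated groups stood apart from control in much the same way. Rank correlation, which no scaling of an array changes, reached at most 0.875 between control and treated arrays and at least 0.966 between different treated groups, which argues against scaling. If slide row and column had added up to the pattern, the nano-TiO2 change would have followed the sum of the nano-ZnO and mixture changes with a slope of about 1, and the slope was 0.482. A shift of the control cultures unrelated to the particles cannot be told apart from a response common to both particles, because there is 1 control condition and both predict a slope near 1 of the mixture change on the mean single change, which was 0.954. That open point may bear on every call against control and on the interaction.

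The overall F test called 2228 IDs between the 4 groups. Only the real grouping among 100 splits of the 8 arrays into 4 pairs, that is 1 split, gave as many. This argues against a chance assignment of the arrays to groups, but the highest other split called 2144. That split kept the control and nano-ZnO pairs and exchanged arrays of nano-TiO2 and the mixture. The 13 other splits that kept the control pair called 1100 to 2144 IDs and the 86 that parted it called 0 to 2, so the count rests mainly on the control arrays. The splits say little on nano-TiO2 against the mixture, and they cannot separate a group from its own slide positions.

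Replicates 1 and 3 of each group were nearly identical. Their spot deviations correlated at 0.807 or more, above every other pair of files, as 2 scans of 1 array would. Separate hybridisations of the same RNA would differ by at least the spot noise if spot deviations were independent between arrays, which gives 0.455. The median squared difference over spot variance was at most 0.317, below that value. Yet spot deviations of replicate 2 and either other replicate correlated at 0.260 to 0.564, and such a shared part lowers the difference. This measure therefore cannot decide against separate hybridisations. No biological explanation was tested for this pattern.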

How the results depend on the processing

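The fits of 12 separate files with and without the scan as a block, the first scan alone, normexp, kept outlier spots and nano-TiO2 against nano-ZnO were chosen only after the data were examined. All 516 values of the 28 changes named by size kept direction and call under every alternative, arrays left out included. Outside the leave-out fits, calls ran from 1759 to 2138 for nano-ZnO, 1733 to 2126 for nano-TiO2 and 1762 to 2140 for the mixture against control, from 1004 to 1833 for the mixture against nano-ZnO, and from 1558 to 2024 for the interaction. The mixture against nano-TiO2 gave 94 calls, and 62 with only these groups in the fit, 564 with 12 separate files and 524 with the scan as a block among them. Replicate numbers were not taken to pair the arrays, since no label ties them to a culture or batch and 1 of the 6 pairs of groups correlated at only 0.072 in the difference of replicate 1 minus 2. The other pairs of groups lay at 0.155 to 0.412, and the number goes with odd or even slide column. With the replicate block this comparison gave 174 calls and 2 fixed-list tags.

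Quantile normalization moved the median of all IDs by 0.18 (nano-ZnO), 0.10 (nano-TiO2), 0.12 (mixture) and -0.17 (interaction), and median centring moved it by 0.10 for nano-ZnO, -0.11 for the mixture against nano-ZnO and -0.12 between the particles. Relative to it, the list's median with nano-ZnO was 0.94, and 1.09 under quantile normalization. Of 1548 fixed-list values, 1419 kept direction and call, 31 lost and 51 gained a call, 30 changed sign and 3 went to 0 with no call in either setting, and 14 with a call changed sign, under quantile normalization or the authors' values. Against nano-ZnO, 3 called tags did so: to 0.31 and 0.31 (called), 0.11 and 0.10 (NE0943, not called), and 0.014 and 0.014 (not called) for the mixture, and to 0.31 and 0.31, 0.11 and 0.10, and 0.042 and 0.042 for nano-TiO2. Another tag had interactions of -0.20 and -0.17 there.

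The fixed list had 11 calls for the mixture against nano-ZnO with the scan as a block, 2 for the mixture against nano-TiO2 in both fits of 12 files, and 4 between the particles under quantile normalization and in the authors' values. Its test called nano-ZnO against control with fry (adjusted p = 0.0142, range over alternatives 0.0142 to 0.870), which asks another question than camera. Its calls ended under quantile normalization, the authors' values and an estimated correlation: adjusted p = 0.406, 0.388 and 0.298 for the mixture against nano-ZnO (range from 0.00107), 0.140, 0.139 and 0.425 against nano-TiO2 (range from 0.00146), and 0.132, 0.116 and 0.143 between the particles (range from 5.76e-06). The correlation of nano-TiO2 and mixture changes was 0.963 with normexp, 0.961 with quantile normalization and 0.960 in the authors' values. The cause was not tested.

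With each array left out, the lone array of a group is assumed to vary like the other groups. Calls were 1823 to 1899, 1806 to 1861 and 1837 to 1889 against control, 1018 to 1332 and 75 to 84 for the mixture against nano-ZnO and nano-TiO2, and 1662 to 1784 for the interaction. The list's adjusted p for the mixture against nano-TiO2 ran from 0.00368 to 0.125, the highest without mixture replicate 2. Correlations of changes ran from 0.892 to 0.926 (nano-ZnO and nano-TiO2), 0.898 to 0.933 (nano-ZnO and mixture) and 0.963 to 0.968 (nano-TiO2 and mixture). The slide as a block was not run, since a scan covers 1 slide, nor were rules for several probes, as each ID has 1. Signal over background limited only the 12 IDs left out and the 11 with a bound.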

Other observations

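The tests of the tags at which the mixture was called lowest were chosen only after these had been seen. Part of the changes came in runs of consecutive locus tags. Counting runs of at least 4 consecutive tags that changed by 2-fold or more in the same direction in all 3 comparisons against control, there were 23 runs, of which 4 rose and 19 fell, while 100000 permuted orders held at most 9 runs. The runs held 17 of the 197 tags that rose in this way and 93 of the 371 that fell. The longest ran over 10 tags from NE0763 to NE0772, with median log2 changes of -3.29 with nano-ZnO, -2.90 with nano-TiO2 and -2.99 with the mixture. The 6 tags from NE0922 to NE0927 had median log2 changes of -3.62 with nano-ZnO, -4.80 with nano-TiO2 and -2.12 with the mixture. Within this run, the mixture lay above nano-TiO2 by 2.33 to 2.94 from NE0924 to NE0927, while the differences at NE0922 (0.36) and NE0923 (0.34) were not called. The 5 tags from NE0779 to NE0783 rose by medians of 1.36, 1.60 and 1.59.

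The mean change of a tag correlated with that of the next tag at 0.436 over 2276 pairs, and the highest of 100000 permuted orders gave 0.0943 (permutation p = 1e-05, 1-sided, the smallest they can give), which argues against a chance order. Spots of neighbouring tags lay no closer together on the array than those of random pairs, with median smallest distances of 10.05 and 10.0 spot positions, which argues against local artefacts of the slide. Joint transcription of neighbouring genes is a candidate explanation that these files cannot test, since they hold no gene positions.

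Of the 47 IDs that start with RNA, a set chosen after the data were examined, 19 fell with the mixture against control by limma. This is a share of 40.4% beside 38.1% of all IDs. Of these 47 IDs, 0 rose (1 at an unadjusted p under 0.05), while 1033 of all 2424 IDs did, and their median was -0.64. With nano-TiO2, 17 fell (36.2%, beside 37.2% of all IDs) and 3 rose (beside 1038 of all 2424 IDs), with a median of -0.45. With nano-ZnO, 9 fell (19.1%, beside 42.1% of all IDs) and 4 rose (beside 944 of all 2424 IDs), with a median of -0.26. The set test gave camera adjusted p = 0.0406 for the mixture (adjusted p = 0.823 with an estimated correlation), 0.184 for nano-TiO2 and 0.523 for nano-ZnO. With the mixture, 11 fell against nano-ZnO (23.4%, beside 20.6% of all IDs), 0 rose and 36 were not called. The set test gave camera adjusted p = 0.000427, and adjusted p = 0.370 with an estimated correlation. Against nano-TiO2 limma called 0, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0231, and adjusted p = 0.569 with an estimated correlation). Between the particles 6 were lower with nano-TiO2 (12.8%, beside 23.6% of all IDs) and 2 higher (beside 946 of all 2424 IDs). The set test gave camera adjusted p = 0.0162, and adjusted p = 0.548 with an estimated correlation. For the interaction 6 lay above the sum (beside 948 of all 2424 IDs) and 4 below (8.51%, beside 36.3% of all IDs), with camera adjusted p = 0.904.

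The tags at which the mixture was called below control and below each single particle stood close together in the numbering. Of these 26 tags, 11 lay between NE1070 and NE1102. The median distance of the 26 tags to the nearest other such tag was 1 tag number, against at least 6 in 100000 permuted orders (permutation p = 1e-05, 1-sided, the smallest they can give), which argues against a chance order of the tags. Neighbouring tags changed together in general, and whether this group goes beyond that was not tested.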
